A study of Homo sapiens with 10 samples.

How the data were processed

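RNA from primary cultures of human airway smooth muscle cells was hybridised to Agilent 1-colour arrays after labelling with Cy3. The cells had received no treatment, or 1 µM of the synthetic glucocorticoid dexamethasone for 4 h or 24 h, and per the labels all cultures were collected at the same time. The design text gives 4 biological replicates per group and states that the authors left out 2 samples on the basis of clustering and diagnostic plots, which leaves 4 untreated arrays, 3 arrays at 4 h and 3 arrays at 24 h. The labels do not say whether the untreated cells received the solvent of the drug, so an effect of the solvent cannot be separated from that of the drug.

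Per the file headers, spot intensities were made with Agilent Feature Extraction 10.1.1.1, while the notes of the submitters give version 9.1. The deposited spot intensity is the background-subtracted and spatially detrended signal on a linear scale, not scaled between arrays, and the files also hold the median intensity of each spot and of its local background. A table by the authors holds group means and fold changes on a log2 scale, a test statistic and a log odds score, and p-values with adjustments over all 41000 probes. The deposited table gives no values per sample, tool or settings. Its p-values matched the statistic at 10 degrees of freedom, and its log2 group means differed by a median of 0.0026 from those of quantile-normalized log2 median intensities.

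Each array had 45015 spots, of which 1639 were controls, and 41000 probes. The analysis took the log2 of the processed intensity minus the 75th percentile of the same array over non-control probes. Control spots and spots with an outlier mark were left out, and spots of the same probe were averaged. In all, 134 probes for chromosome Y, XIST and TSIX were left out of everything, so 40866 remained. Current gene symbols came from a RefSeq gene table, through the Entrez gene ID for 28671 probes and through the accession for 325. For 947 probes the symbol of the deposited table was kept, and 10923 had no gene name. Probes had to be well above background on every array of at least 1 group and unmarked on at least 2 arrays of each group, and each gene was represented by its probe with the highest mean over all 10 arrays. This left 23064 genes and unnamed transcripts, of which 16399 had a gene name.

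Groups were compared with limma 3.58.1 in R 4.3.3, with a mean for each group, moderated 2-sided tests and Benjamini-Hochberg adjustment over all 23064 genes, at an adjusted p of 0.05. Changes are log2 fold changes with the standard error (SE) of the fit. Where a gene was not well above background on any array of a group, its fold is given as a lower bound against the background limit ("at least"). The precision is limited by the number of arrays: the median SE was 0.12, and the median half-width of the 95% interval was 0.27 on the log2 scale. Values missing after the removal of marked spots (863 among the tested genes) were not filled in the main fit. They were filled for the tests of gene lists and gene ontology terms, and for the mean of all probes of a gene.

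In all, 24 gene lists with 529 genes, 5 of them markers of other cell types, were written before the data were examined. Each was tested with camera in limma at a preset correlation of 0.01, adjusted over the 24 lists, again with an estimated correlation, and with fry. The genes named in the text were also set by a rule written before the data were examined. It took the 10 highest and 10 lowest changes at 4 h and at 24 h, and the 6 highest and 6 lowest between the times, among genes with a proper symbol, an adjusted p under 0.05 and no overlap of the arrays compared. It added KLF15, NR3C1, FKBP5, TSC22D3, PER1 and DUSP1 whatever their values, and up to 4 members of each list with the smallest adjusted p, or up to 2 members as values where none passed. Not every gene that the rule gives is named in the text. Gene ontology terms of the array annotation with 15 to 300 tested genes (582 terms) were tested with camera after the lists.

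The alternatives chosen before the data were examined were quantile normalization, no filter on dim probes, a filter for signal on all 10 arrays, the slide as a block, replicate numbers as a block, only the 2 groups compared, moderation with a trend and robust prior, array weights, the mean of all probes of a gene, every probe on its own, leaving out each array, and, for the correlation of the changes at both times, a split of the untreated arrays. Alternatives chosen after seeing the data were normexp background correction (offset 50) on the median intensity, a rebuild of the authors' normalization, scaling to the array median, outlier spots kept, leaving out each slide, and the slide block with an estimated correlation. The fit was tested on simulated data with 200 changed genes among 23064. At a log2 change of 1 it recovered 76.1% of the changed genes in each comparison, and false calls numbered 6 at 4 h, 9 at 24 h and 6 between the times. At a log2 change of 0.5 it recovered 35.8% at 4 h, 29.9% at 24 h and 29.9% between the times. The arrays in these simulations were independent, so the shares and false calls leave out any difference between slides. The data gave 2219 calls at 4 h, 8896 at 24 h and 7083 between the times, against 200 changed genes here. With so few changed genes the adjustment is stricter, so these shares do not tell how many changes were missed in the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.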

Results

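Gene expression was measured in cultured human airway smooth muscle cells, the contractile cells of the airway wall, on 10 arrays: 4 of untreated cells, 3 of cells given 1 µM dexamethasone for 4 h and 3 of cells given it for 24 h. The 75th percentile of the probe signal ranged from 1047 to 1657 intensity units between arrays, the median signal from 105 to 163 and the median local background from 19 to 20. Between 76.9% and 80.6% of the probes were well above background. Arrays of the same group correlated across genes at 0.985 to 0.997. The first principal component held 51.0% of the variance and the second 22.7%. The arrays came from 3 slides, each scanned in its own run. Slide 1 held untreated replicates 1 and 2 and 4 h replicate 3, slide 2 held untreated replicate 4, 4 h replicate 2 and 24 h replicates 1 and 3, and slide 3 held 1 array of each group. Leaving out slide 2 therefore left a single array at 24 h, and results at 24 h under that setting rest on it. Of the sum of squares within groups, 77.1% went with the slide, where chance gives 28.6%.

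**Figure D1:**
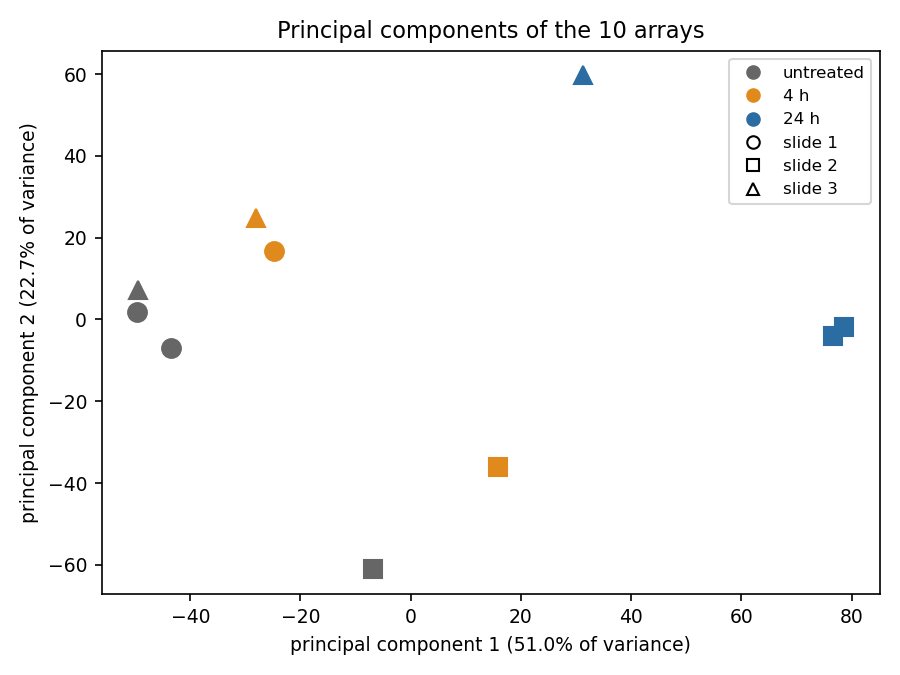
Scores of the 10 arrays on the first and second principal components of all genes measured on every array, with colours for the groups and symbols for the slides. The first component holds 51.0% of the variance and the second 22.7%; on the second, untreated replicate 4 and 4 h replicate 2, both on slide 2, lie below the other 8 arrays.

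The first comparison asked which genes had changed after 4 h of dexamethasone. Of 23 cytokines and chemokines 12 fell, and of 28 known glucocorticoid-induced genes 21 rose. LIF, a cytokine of the interleukin 6 family, fell by 6.98 ± 0.11 on the log2 scale (SE, 3 treated and 4 untreated arrays), or 127-fold, and the growth factor of granulocytes and macrophages CSF2 fell by 5.62 ± 0.09. IL6 fell by 4.71 ± 0.10, and the neutrophil attractant CXCL8 was at least 9.44-fold lower, being above background on all untreated arrays and on none at 4 h; without the arrays of slide 1 its call ended (adjusted p = 0.0762). The transcription factor KLF15 rose by 5.47 ± 0.16 (44.4-fold). That size depends on the processing: the untreated signal of KLF15 was low, at -6.53 to -7.29 on the log2 scale, and its deposited change was 4.01. PNMT, the enzyme that turns noradrenaline into adrenaline, was at least 29.1-fold higher than in untreated cells, where it was not above background.

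Among the other genes with the lowest values at 4 h, IER3, an early stress response gene, fell by 4.85 ± 0.08, and the interleukin 6 family member IL11 fell by 4.40 ± 0.12. The tight junction gene CLDN14 fell by 4.38 ± 0.20, the death receptor ligand FASLG fell by 3.77 ± 0.08, and PTGS2, which encodes the inducible cyclooxygenase, fell by 3.64 ± 0.08. ENC1 fell by 4.44 ± 0.85, a size that rested on single arrays: it was -3.10 without 4 h replicate 4, -5.14 without 4 h replicate 2 and -5.08 without 4 h replicate 3. Among the highest, IL22RA1, a subunit of the interleukin 22 receptor, was at least 11.1-fold higher. PDK4, a kinase that inhibits pyruvate dehydrogenase, rose by 3.87 ± 0.17, and FKBP5, a cochaperone of the glucocorticoid receptor, by 3.79 ± 0.13. The Notch target HEYL rose by 3.56 ± 0.27, the Wnt feedback gene AXIN2 by 3.40 ± 0.08, TIPARP by 3.34 ± 0.12 and the actin-binding gene XIRP1 by 3.27 ± 0.27. In the deposited table, the probe of KLF15 lies on chromosome 3 at 127544379 to 127544438 and that of LIF on chromosome 22 at 28966713 to 28966772, and the genome build is not given in the sources used here.

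In the list of known glucocorticoid-induced genes, 21 of 28 rose and 1 fell at 4 h, while 6 did not pass the test. Adjusted over the list alone, 23 passed. Beyond KLF15 and FKBP5, TSC22D3, which encodes a leucine zipper protein with anti-inflammatory action, rose by 2.72 ± 0.11, and the glutamine synthetase gene GLUL by 2.08 ± 0.08. The MAP kinase phosphatase gene DUSP1 rose by 0.94 ± 0.10. The median of the list was 1.01 (camera, adjusted p = 2.15e-25; adjusted p = 0.0361 with an estimated correlation). Metallothioneins, small metal-binding proteins, rose in 8 of 11 cases and 8 passed adjusted over the list alone, with MT1E at 1.29 ± 0.14 (camera, adjusted p = 1.87e-09; adjusted p = 0.0879 with an estimated correlation). The calls of MT1L (0.80 ± 0.11) and MT1A (0.93 ± 0.13, from 2 arrays at 4 h) ended under quantile normalization, at adjusted p = 0.220 and 0.368.

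Of 23 cytokines and chemokines, 12 fell, none rose and 11 did not pass; adjusted over the list alone, 13 passed. Their median was -0.96 (camera, adjusted p = 1.19e-16; adjusted p = 0.0361 with an estimated correlation). Of 23 genes of the NF-kB pathway and other inflammatory mediators, 12 fell and 1 rose, and 17 passed adjusted over the list alone. After PTGS2, the hyaluronan-binding TNFAIP6 fell by 1.98 ± 0.08, the apoptosis inhibitor BIRC3 by 1.51 ± 0.09 and the endotoxin receptor TLR4 by 1.01 ± 0.06 (camera, adjusted p = 9.59e-09; adjusted p = 0.0903 with an estimated correlation). Of 21 immediate early genes, which respond to growth stimuli within minutes, 14 fell and 4 rose, and 18 passed adjusted over the list alone. Among them NR4A3 fell by 2.85 ± 0.16, EGR3 by 2.62 ± 0.13 and EGR2 by 1.92 ± 0.10 (camera, adjusted p = 2.55e-08; adjusted p = 0.105 with an estimated correlation). Growth factors and IGF binding proteins fell in 10 of 24 cases and rose in 1, with 13 passing adjusted over the list alone. HBEGF, a ligand of the epidermal growth factor receptor, fell by 3.12 ± 0.07, NRG1 by 2.24 ± 0.15, the vascular growth factor VEGFA by 1.83 ± 0.08 and FGF2 by 1.65 ± 0.07 (camera, adjusted p = 8.05e-08; adjusted p = 0.0931 with an estimated correlation).

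Of 28 genes of the TGF-beta, activin and BMP pathways, 9 fell and 5 rose, and 17 passed adjusted over the list alone. The activin subunit gene INHBA fell by 1.83 ± 0.11, BMP2 by 0.82 ± 0.07 and FST by 0.68 ± 0.06, while the coreceptor gene TGFBR3 rose by 1.62 ± 0.11. The list passed as lower (camera, adjusted p = 0.0159), but not with an estimated correlation (adjusted p = 0.732). Nor did it pass without untreated replicate 4 (adjusted p = 0.0805) or 4 h replicate 3 (adjusted p = 0.130). The call also ended with the replicate numbers of the source names as a block (adjusted p = 0.0970). Of 20 genes of the unfolded protein and heat shock responses, 6 fell and none rose, and 8 passed adjusted over the list alone. The heme-degrading enzyme gene HMOX1 fell by 1.33 ± 0.10 (3 untreated arrays), SESN2 by 0.97 ± 0.12, DDIT3 by 0.80 ± 0.10 and TRIB3 by 0.64 ± 0.13 (camera, adjusted p = 0.00201; adjusted p = 0.414 with an estimated correlation), and the call of TRIB3 ended when scaled to the array median (adjusted p = 0.0649). Cell cycle and DNA replication genes gave 0 of 30 past the threshold, also adjusted over the list alone. CDC6 had -0.21 ± 0.06, which passed with the slide as a block (adjusted p = 0.0381), and MCM6 0.18 ± 0.06. The median of the list, 0.16, ranked high among all genes (camera, adjusted p = 0.00201; adjusted p = 0.732 with an estimated correlation), which did not hold without 4 h replicate 3 (adjusted p = 0.137) or leaving out slide 3 (adjusted p = 0.0887).

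The other fixed lists did not pass at 4 h. Of 30 receptors and regulators of airway contraction and relaxation, 6 fell and 5 rose (14 adjusted over the list alone): the bradykinin receptor genes BDKRB1 and BDKRB2 fell by 3.28 ± 0.10 and 2.44 ± 0.11, the G protein regulator RGS4 fell by 1.81 ± 0.10, and the prostaglandin receptor gene PTGER2 rose by 1.71 ± 0.06 (adjusted p = 0.611 for the list). Of 22 matrix proteases and inhibitors, 6 fell and 2 rose (9 adjusted over the list alone). SERPINB2 had -1.29 ± 0.15, PLAUR -1.06 ± 0.11, PLAU -0.96 ± 0.08 and ADAMTS9 1.19 ± 0.16, a call that normexp correction ended (adjusted p = 0.0821). That list had adjusted p = 0.0664, and passed as lower without untreated replicate 1 (adjusted p = 0.0405), untreated replicate 2 (adjusted p = 0.0390) or 4 h replicate 2 (adjusted p = 0.00832) and with the slide as a block (adjusted p = 0.0158). It passed also under quantile normalization (adjusted p = 0.0210), with no filter on dim probes (0.0251), with normexp correction (0.0168), with the normalization of the authors rebuilt (0.0140) and leaving out slide 1 (0.0376) or slide 2 (0.0480). Of 25 contractile and cytoskeletal genes, 5 rose and 2 fell (10 adjusted over the list alone). The intermediate filament gene DES had 1.42 ± 0.14, SYNPO2 0.68 ± 0.10 and VCL 0.59 ± 0.07 (adjusted p = 0.519 for the list). Of 30 matrix genes, 1 passed, also adjusted over the list alone: HAS2, a hyaluronan synthase gene, fell by 2.25 ± 0.14 (adjusted p = 0.758 for the list; adjusted p = 0.0121 without 4 h replicate 2).

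Circadian clock genes fell in 6 of 19 cases and rose in 3 at 4 h (10 adjusted over the list alone). PER1 rose by 3.10 ± 0.15 and CIART by 1.28 ± 0.14, while BHLHE40 fell by 1.03 ± 0.12 and BMAL1 by 0.67 ± 0.08 (adjusted p = 0.497 for the list). Of 18 genes for the receptor, its chaperones and steroid-handling enzymes, 3 rose and 2 fell (5 adjusted over the list alone). The glucocorticoid receptor gene NR3C1 fell by 0.84 ± 0.06 and the mineralocorticoid receptor gene NR3C2 by 1.46 ± 0.15, while HSD11B1, whose enzyme activates cortisone, rose by 1.25 ± 0.08 (adjusted p = 0.522 for the list). Adipogenic and lipid genes had 2 higher and 2 lower of 21 (4 adjusted over the list alone). PLIN2 had 0.88 ± 0.07 (adjusted p = 0.519 for the list). Interferon-stimulated genes had 1 higher and 2 lower of 22 (3 adjusted over the list alone). IFI44L had 1.03 ± 0.13, GBP1 -0.61 ± 0.07 and IFIT2 -0.55 ± 0.08 (adjusted p = 0.928 for the list). In amino acid enzymes, 1 of 23 passed, also adjusted over the list alone, which was GLUL (adjusted p = 0.497 for the list). Ribosomal protein genes, kept as a reference, gave 0 of 30, also adjusted over the list alone (adjusted p = 0.774 for the list). RPS27A had 0.10 ± 0.10, from 2 untreated arrays. The ribosomal list passed as higher without untreated replicate 4 (adjusted p = 0.000867) and as lower leaving out slide 1 (adjusted p = 0.00346). It passed as higher also with the replicate numbers of the source names as a block (adjusted p = 0.0202).

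Markers of other cell types were mostly below the threshold at 4 h. Epithelial markers had KRT18 lower, at -0.94 ± 0.13, of 11 (1 adjusted over the list alone), and leukocyte markers had KIT at 1.65 ± 0.09, CD163 at 1.41 ± 0.22 and CSF1R at -0.64 ± 0.12 past it, of 11 (3 adjusted over the list alone). None of 7 endothelial markers (TEK -0.26 ± 0.09), 12 fibroblast markers (CD34 0.39 ± 0.14) or 8 neural markers (GAP43 -0.12 ± 0.12) passed, also adjusted over each list alone. With the slide as a block, TEK (-0.29, adjusted p = 0.0206) and VWF (-0.44, adjusted p = 0.0125) were lower. The adjusted p of these lists lay between 0.297 for the endothelial markers and 0.965 for the neural markers. All of these marker genes counted as tested were above background on the arrays of at least 1 group of this culture.

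Over all genes, 2219 of 23064 changed at 4 h (limma, Benjamini-Hochberg), 1064 higher and 1155 lower, and 615 changed at least 2-fold (311 with normexp correction on the median signal). With array weights, 1733 were higher and 1681 lower. Over all 23064 genes, the 4 h and untreated arrays did not overlap in 18.5%, where chance gives 5.71%. With the slide as a block, 3572 genes passed, among them 2208 of the 2219. The median, mean and camera direction differed in sign for the contractile, clock, interferon, leukocyte and neural lists. Single arrays ended 4 further calls of the naming rule: MYLK (-0.27 ± 0.06; adjusted p = 0.0543 without untreated replicate 1, 0.0599 without untreated replicate 3, 0.0845 without 4 h replicate 3, 0.0958 without 4 h replicate 4), SCD (-0.37 ± 0.09; 0.0782 without untreated replicate 3, 0.0616 without untreated replicate 4, 0.115 without 4 h replicate 3, 0.114 without 4 h replicate 4), HSD11B2 (0.87 ± 0.19; 0.0611, 0.0646 and 0.0509 without untreated replicates 1, 2 and 4, 0.0758 and 0.0900 without 4 h replicates 2 and 4), and PPARG (0.30 ± 0.08; ended without any single array except 24 h replicate 2, up to 0.148 without 4 h replicate 3).

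**Figure D2:**
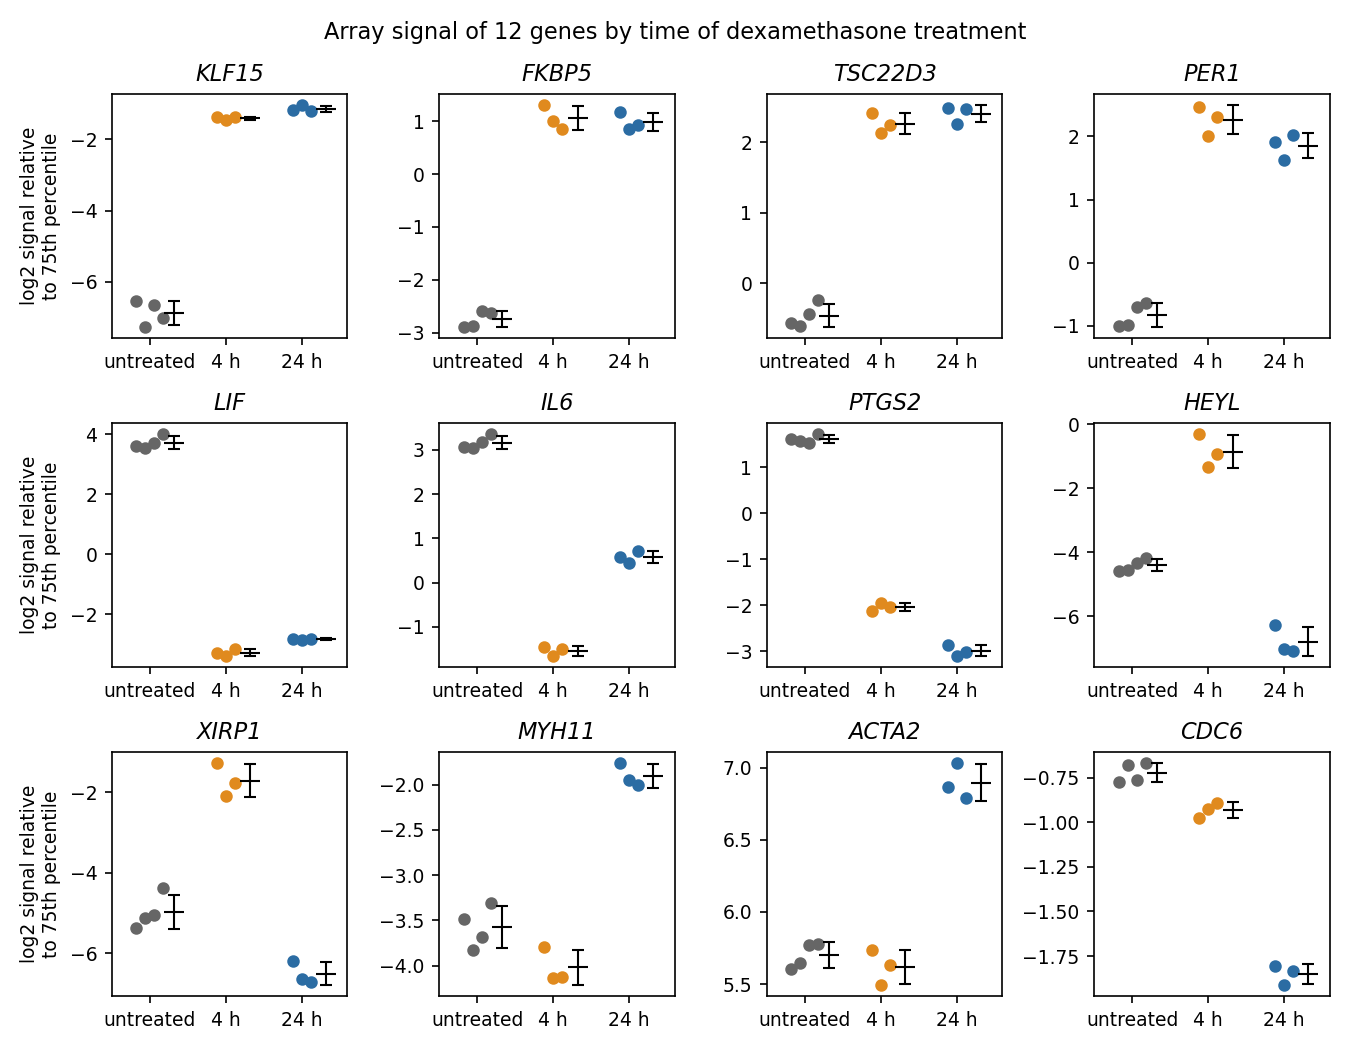
Log2 signal relative to the 75th percentile of each array for 12 genes (points, one per array) in untreated cells and after 4 h and 24 h of dexamethasone, with the mean and SD of each group beside the points. KLF15, FKBP5, TSC22D3 and PER1 were higher at both times, LIF, IL6 and PTGS2 lower at both, HEYL and XIRP1 higher at 4 h and lower at 24 h, and MYH11 and ACTA2 higher and CDC6 lower at 24 h.

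The second comparison asked which genes had changed after 24 h. LIF remained far below the untreated cells, at -6.54 ± 0.11 (SE, 3 treated and 4 untreated arrays), and HBEGF fell by 6.19 ± 0.07, or 73.2-fold. FASLG was at least 24.7-fold lower. KLF15 was higher by 5.74 ± 0.16, where its deposited change was 4.24. ANGPTL7, an angiopoietin-like secreted protein, was at least 47.1-fold higher, being above background on the 24 h arrays alone. Of 30 cell cycle and DNA replication genes, 28 fell.

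Further genes with the lowest values at 24 h were the growth response factor EGR2, at -5.96 ± 0.10, and CLDN14 at -5.53 ± 0.20. IL11 fell by 5.34 ± 0.12, TNFAIP6 fell by 5.21 ± 0.08 and the AP-1 factor FOSB fell by 4.87 ± 0.16. KRT18P45, a pseudogene of the keratin gene KRT18, had -5.32 ± 1.75. That value rested on 24 h replicate 2 (-2.56 without it, and -6.70 without 24 h replicate 1 or 3), and the call ended without any of the 4 untreated arrays (adjusted p = 0.0654 to 0.0771) or any of the 3 arrays at 4 h (adjusted p = 0.0541 to 0.0572). Among the highest were CCDC192, the fat cell hormone gene LEP and the acute phase gene SAA1, which were above background on 1, 2 and 3 of the 4 untreated arrays and on all arrays at 24 h. The size of their rise is uncertain for that reason. MOB3B was at least 24.1-fold and PNMT at least 13.5-fold higher. The transcription factor ZBTB16 rose by 5.12 ± 0.27, the matrix-associated SPARCL1 by 4.94 ± 0.09 and the natriuretic peptide protease CORIN by 4.69 ± 0.17. In ZBTB16 and SPARCL1, untreated replicate 4 lay below the other 3 untreated arrays, at -4.31 and -5.91.

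Glucocorticoid-induced genes rose in 22 of 28 cases and fell in 4 at 24 h, and 27 passed adjusted over the list alone. The monoamine oxidase gene MAOA rose by 3.86 ± 0.13, the nucleotide triphosphatase SAMHD1 by 3.76 ± 0.08, FKBP5 by 3.72 ± 0.13, GLUL by 3.06 ± 0.08, TSC22D3 by 2.86 ± 0.11 and DUSP1 by 0.97 ± 0.10 (camera, adjusted p = 1.33e-10; adjusted p = 0.310 with an estimated correlation). Cytokines and chemokines fell in 16 of 23 cases and rose in 1, and 18 passed adjusted over the list alone. CCL7 had -4.36 ± 0.11 and CSF2 -4.18 ± 0.09 (camera, adjusted p = 3.70e-10; adjusted p = 0.201 with an estimated correlation). Growth factors fell in 16 of 24 cases and rose in 3, and 19 passed adjusted over the list alone. NRG1 had -4.11 ± 0.15, VEGFA -2.57 ± 0.08 and FGF2 -2.45 ± 0.07 (camera, adjusted p = 6.40e-05; adjusted p = 0.352 with an estimated correlation). Immediate early genes fell in 12 of 21 cases and rose in 6, and 19 passed adjusted over the list alone. IER3 had -3.59 ± 0.08 and EGR3 -2.88 ± 0.13 (camera, adjusted p = 0.00312; adjusted p = 0.524 with an estimated correlation). Metallothioneins rose in 8 of 11 cases, 8 also adjusted over the list alone. MT1E had 1.38 ± 0.16 and MT1B 1.08 ± 0.13, both from 2 arrays at 24 h, since the spots of 24 h replicate 2 were marked as outliers (camera, adjusted p = 0.000344, and 0.352 with an estimated correlation). MT1L, from the same 2 arrays, had 0.97 ± 0.12, a call that quantile normalization ended (adjusted p = 0.0541). Leaving out slide 2 left only 24 h replicate 2, on which MT1E, MT1B and MT1L had no value. The call of the list ended there, but that test rests on a single array and on the remaining members.

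The cell cycle list had 28 of 30 genes lower and none higher at 24 h, and 29 passed adjusted over the list alone. The replication licensing factor CDC6 fell by 1.13 ± 0.06, the mitotic kinase AURKB by 0.98 ± 0.09, the replication factor CDC45 by 0.96 ± 0.08 and the cyclin CCNE1 by 0.56 ± 0.06. The median was -0.68 (camera, adjusted p = 1.33e-10; adjusted p = 0.352 with an estimated correlation). Contractile and cytoskeletal genes rose in 12 of 25 cases and fell in 5, and 19 passed adjusted over the list alone. PPP1R14A, an inhibitor of myosin phosphatase, rose by 3.07 ± 0.15, smooth muscle myosin MYH11 by 1.67 ± 0.14 and smooth muscle actin ACTA2 by 1.20 ± 0.09 (camera, adjusted p = 0.00914; adjusted p = 0.524 with an estimated correlation). Interferon-stimulated genes rose in 11 of 22 cases and fell in 2, and 13 passed adjusted over the list alone. IFI44L had 2.63 ± 0.13, IFIT2 1.70 ± 0.08, STAT2 0.78 ± 0.07 and GBP1 -0.69 ± 0.07 (camera, adjusted p = 0.00284; adjusted p = 0.524 with an estimated correlation).

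Unfolded protein and heat shock response genes fell in 10 of 20 cases and rose in 3 at 24 h, and 13 passed adjusted over the list alone. TRIB3 had -1.66 ± 0.13, HMOX1 -1.13 ± 0.10 (3 untreated arrays), HSPH1 -0.80 ± 0.07 and DNAJB9 -0.74 ± 0.06 (camera, adjusted p = 0.00823; adjusted p = 0.524 with an estimated correlation). Matrix proteases and inhibitors fell in 12 of 22 cases and rose in 5, and 18 passed adjusted over the list alone. The stromelysin MMP10 fell by 3.45 ± 0.11 and the collagenase MMP1 by 2.63 ± 0.12. ADAMTS1 rose by 1.85 ± 0.08 (camera, adjusted p = 0.0188 for the list, and 0.524 with an estimated correlation). The call of the protease list ended without 24 h replicate 2 (adjusted p = 0.0586). It also ended with the replicate numbers of the source names as a block (adjusted p = 0.0655). Adipogenic and lipid genes rose in 12 of 21 cases and fell in 3, with 15 passing adjusted over the list alone. PLIN2, which coats lipid droplets, rose by 1.01 ± 0.07 and the fat cell regulator PPARG by 0.76 ± 0.08, while the desaturase gene SCD was lower, at -1.10 ± 0.09 (camera, adjusted p = 0.0367; adjusted p = 0.524 with an estimated correlation). The call of the lipid list ended with the slide as a block (adjusted p = 0.0683), under quantile normalization (adjusted p = 0.0502), with signal required on all 10 arrays (adjusted p = 0.0917), leaving out slide 1 or slide 2 (adjusted p = 0.0762 and 0.158), and without untreated replicate 1 (adjusted p = 0.0531), 24 h replicate 1 (adjusted p = 0.0575) or 24 h replicate 3 (adjusted p = 0.0618).

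Several lists that did not pass at 24 h held changes in both directions. NF-kB and other inflammatory genes had 10 higher and 11 lower of 23 (21 adjusted over the list alone). PTGS2 had -4.60 ± 0.08, the adhesion receptor VCAM1 -2.77 ± 0.18 and RELB -1.38 ± 0.10 (adjusted p = 0.193 for the list). Receptors and regulators of airway contraction and relaxation had 9 higher and 11 lower of 30 (22 adjusted over the list alone): BDKRB1 fell by 4.00 ± 0.10, BDKRB2 by 1.97 ± 0.11 and RGS4 by 1.28 ± 0.10 (adjusted p = 0.455 for the list). TGF-beta, activin and BMP genes had 11 higher and 12 lower of 28 (24 adjusted over the list alone). BMP4 had 2.36 ± 0.16, FST -2.05 ± 0.06, SKIL -1.72 ± 0.11 and INHBA -1.52 ± 0.11 (adjusted p = 0.963 for the list). Matrix genes had 11 higher and 4 lower of 30 (15 adjusted over the list alone). COL11A1 had 2.00 ± 0.08, COL8A1 1.91 ± 0.07, HAS2 -2.63 ± 0.14 and the proteoglycan VCAN -0.82 ± 0.08 (adjusted p = 0.32 for the list).

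Clock genes had 7 higher and 9 lower of 19 at 24 h (16 adjusted over the list alone). PER1 had 2.69 ± 0.15, BHLHE40 -3.09 ± 0.12, PER3 -2.35 ± 0.11 and PER2 -2.16 ± 0.10 (adjusted p = 0.32 for the list). Amino acid enzymes had 8 higher and 6 lower of 23 (14 adjusted over the list alone). DBT had 1.00 ± 0.07 and BCAT2 0.81 ± 0.06 (adjusted p = 0.32 for the list). Among genes for the receptor and steroid handling, 4 of 18 rose and 8 fell (12 adjusted over the list alone): HSD11B1 rose by 2.76 ± 0.08 and NCOA3 by 0.60 ± 0.07, and NR3C1 fell by 1.32 ± 0.06 and NR3C2 by 1.24 ± 0.15 (adjusted p = 0.374 for the list). Ribosomal protein genes gave 0 of 30, also adjusted over the list alone (adjusted p = 0.775 for the list), although 4 were lower with the slide as a block and the list passed as lower leaving out slide 1 (adjusted p = 0.00474).

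Epithelial markers had 5 lower and 1 higher of 11 at 24 h (6 adjusted over the list alone). KRT18 had -2.43 ± 0.13, KRT19 -0.70 ± 0.10, KRT8 -0.54 ± 0.11 and MUC1 1.15 ± 0.18 (adjusted p = 0.0631 for the list). The list passed as lower under some other ways of processing: quantile normalization (adjusted p = 0.0403), the mean of all probes (0.0393), normexp correction (0.0454), the normalization of the authors rebuilt (0.0246), scaling to the array median (0.0292) and outlier spots kept (0.0490). It also passed without 24 h replicate 2 (adjusted p = 0.0288), without untreated replicate 4 (0.0499) and leaving out slide 3 (0.0176), but not with the slide as a block (0.112). Nor did it pass with no filter on dim probes, with signal required on all 10 arrays, with replicate numbers as a block, without any of the other 8 arrays or leaving out slide 1 or slide 2. Fibroblast markers had 6 higher of 12 (6 adjusted over the list alone). DPT had 1.27 ± 0.23, CD34 0.82 ± 0.14, PDGFRA 0.71 ± 0.06 and PDPN 0.36 ± 0.07 (adjusted p = 0.112 for the list; adjusted p = 0.0354 without untreated replicate 4 and 0.0421 with no filter on dim probes). Leukocyte markers had CD163 at 2.74 ± 0.22, KIT at 2.15 ± 0.09 and CSF1R at -1.94 ± 0.12 past the threshold, of 11 tested (3 adjusted over the list alone; adjusted p = 0.963 for the list). Of 8 neural markers 2 were lower (2 adjusted over the list alone), GAP43 at -3.09 ± 0.12 (above background on 1 of 3 arrays at 24 h) and TUBB3 at -0.47 ± 0.07 (adjusted p = 0.179 for the list). Of 7 endothelial markers 2 were lower (3 adjusted over the list alone), VWF at -0.76 ± 0.14 and FLT1 at -0.35 ± 0.10 (adjusted p = 0.294 for the list), and the call of FLT1 ended without untreated replicate 2 (adjusted p = 0.0519), untreated replicate 3 (adjusted p = 0.0551), 24 h replicate 2 (adjusted p = 0.0694) or 24 h replicate 3 (adjusted p = 0.0807).

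In total 8896 of 23064 genes changed at 24 h (limma, Benjamini-Hochberg), 5012 higher and 3884 lower, and 1883 changed at least 2-fold (983 with normexp correction, 2923 with array weights). With array weights the balance turned, with 6663 higher and 6940 lower. Among all genes tested, the 24 h and untreated arrays did not overlap in 42.7%, where chance gives 5.71%. With the slide as a block, 10692 genes passed, among them 8474 of the 8896, although slide 1 held no 24 h array. The TGF-beta, leukocyte and ribosomal lists differed in sign between median and mean.

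**Figure D3:**
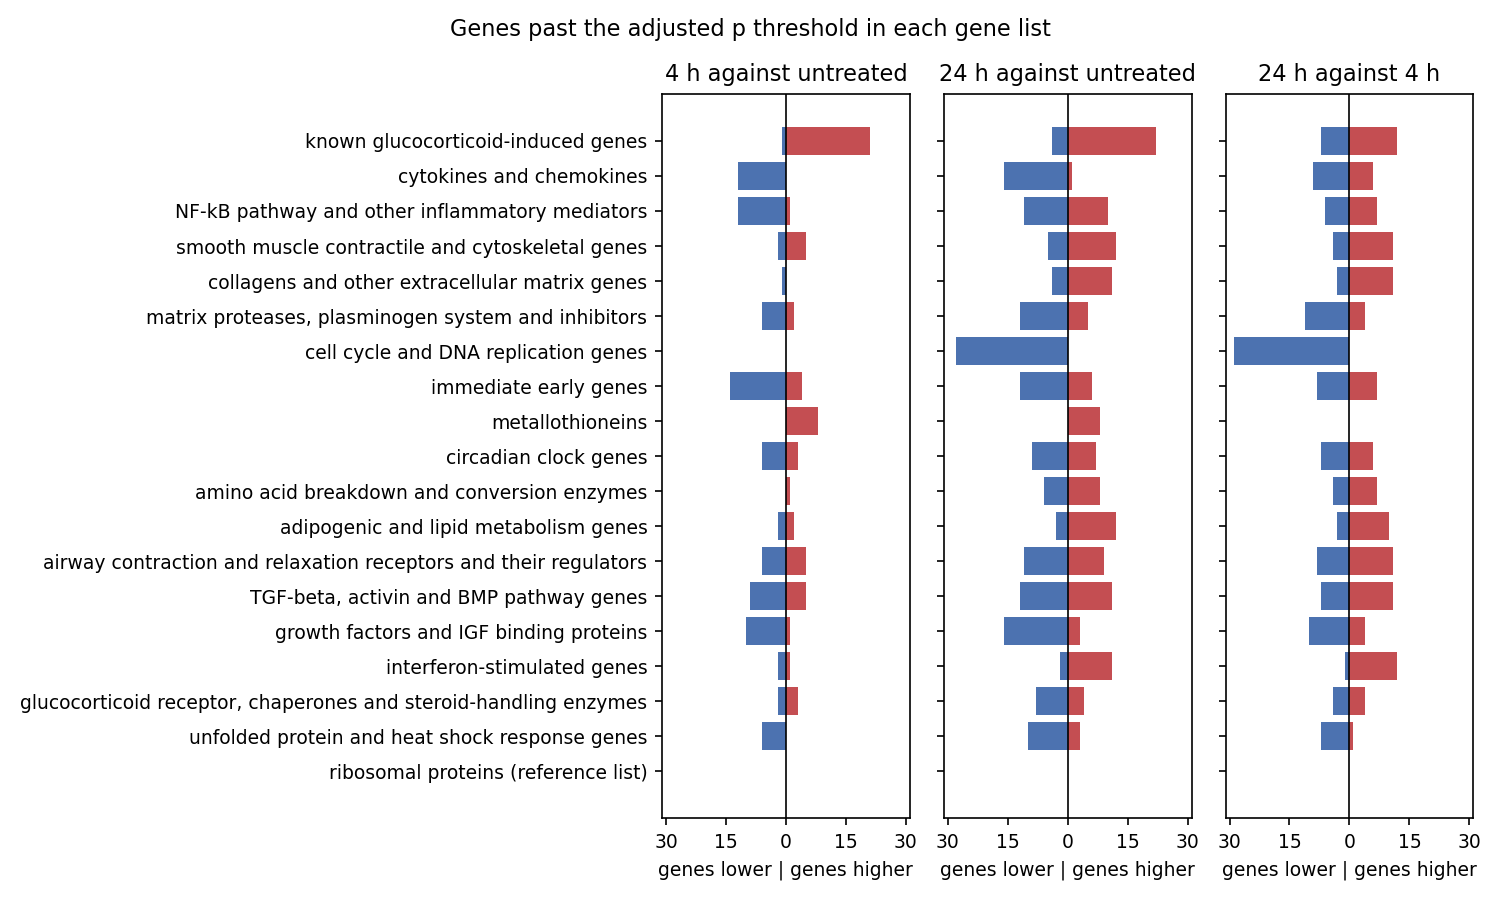
Number of genes past the adjusted p of 0.05 in 19 fixed gene lists, higher to the right (red) and lower to the left (blue), for 4 h against untreated, 24 h against untreated and 24 h against 4 h. Cell cycle and DNA replication genes had 0 past the threshold at 4 h, 28 lower at 24 h and 29 lower at 24 h against 4 h.

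The third comparison tested the difference between 24 h and 4 h itself. HEYL fell by 5.95 ± 0.29 between 4 h and 24 h (SE, 3 and 3 arrays), from 3.56 above untreated cells at 4 h to -2.39 at 24 h. XIRP1, at 3.27 and then -1.53, fell by 4.79 ± 0.29. The deposited changes at 24 h against untreated cells were smaller, at -1.18 for HEYL and -0.76 for XIRP1. Other genes that fell between the times were EGR2 at -4.04 ± 0.10 and the annexin gene ANXA10 at -3.93 ± 0.17. HS3ST1, a heparan sulfate sulfotransferase gene, had -4.84 ± 0.95, and was above background on 1 of 3 arrays at 24 h (-6.16 without 24 h replicate 1 and -3.81 without 24 h replicate 2). ANGPTL7 was at least 44.2-fold higher at 24 h than at 4 h, the matrix protease MMP7 was at least 6.54-fold higher, and CORIN rose by 4.40 ± 0.18 and LEP by 4.36 ± 0.17. SAA1 and CCDC192 also rose, by an uncertain size, since each was above background on 2 of 3 arrays at 4 h.

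Several of the genes fixed in advance gave no difference past the threshold between 24 h and 4 h: KLF15 had 0.27 ± 0.17 (adjusted p = 0.306), TSC22D3 0.14 ± 0.12 (adjusted p = 0.436), DUSP1 0.03 ± 0.11 (adjusted p = 0.857) and FKBP5 -0.07 ± 0.14 (adjusted p = 0.739). PER1 had -0.41 ± 0.16 (adjusted p = 0.0849), which passed with the slide as a block (adjusted p = 0.00073). NR3C1 fell further, by 0.48 ± 0.06. Of 28 glucocorticoid-induced genes, 12 were higher at 24 h and 7 lower (20 adjusted over the list alone). MAOA had 2.95 ± 0.14, SAMHD1 2.73 ± 0.09 and the Ras-related gene RASD1 -1.89 ± 0.09 (adjusted p = 0.105 for the list; adjusted p = 0.0256 without 4 h replicate 2, 0.0327 with no filter on dim probes and 0.0308 with normexp correction).

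Cell cycle genes were lower at 24 h than at 4 h in 29 of 30 cases, 29 also adjusted over the list alone. AURKB had -1.22 ± 0.10, CDC45 -0.97 ± 0.09, CDC6 -0.92 ± 0.06 and CCNE1 -0.66 ± 0.06. Their median was -0.85 (camera, adjusted p = 1.26e-15; adjusted p = 0.779 with an estimated correlation). Interferon-stimulated genes were higher in 12 of 22 cases and lower in 1, 14 adjusted over the list alone, with IFIT2 at 2.25 ± 0.08, IFI44L at 1.60 ± 0.13 and IFIT3 at 1.04 ± 0.11 (camera, adjusted p = 0.00253; adjusted p = 0.779 with an estimated correlation). Contractile genes were higher in 11 of 25 cases and lower in 4, 16 adjusted over the list alone, with PPP1R14A at 2.41 ± 0.16, MYH11 at 2.11 ± 0.15 and ACTA2 at 1.28 ± 0.09 (camera, adjusted p = 0.0353; adjusted p = 0.779 with an estimated correlation). Lipid genes were higher in 10 of 21 cases and lower in 3, 15 adjusted over the list alone, with the lipase gene LIPE at 0.94 ± 0.12 (camera, adjusted p = 0.0353; adjusted p = 0.779 with an estimated correlation). The calls of the contractile and lipid lists ended with the slide as a block (adjusted p = 0.0842 and 0.0590), under quantile normalization (adjusted p = 0.0553 for both) and without 4 h replicate 3 (adjusted p = 0.0519 for both), and that of the lipid list also without 24 h replicate 3 (adjusted p = 0.0546) and with signal required on all 10 arrays (adjusted p = 0.103). Leaving out slide 1 ended both calls (adjusted p = 0.0531), as did leaving out slide 2 (adjusted p = 0.0753 and 0.0975), and leaving out slide 3 ended that of the contractile list (adjusted p = 0.0551).

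No other list passed between the times, and the adjusted p values below are those of the lists. Cytokines had 6 higher and 9 lower of 23 (15 adjusted over the list alone). IL6 had 2.13 ± 0.11, CSF2 1.45 ± 0.10, the alarmin IL33 -2.09 ± 0.12 and CCL7 -1.66 ± 0.12 (adjusted p = 0.237). Inflammatory mediators had 7 higher and 6 lower of 23 (16 adjusted over the list alone). IRF1 had 2.17 ± 0.13, BIRC3 2.11 ± 0.09, TLR4 1.77 ± 0.07 and TNFAIP6 -3.23 ± 0.09 (adjusted p = 0.773; median and mean differed in sign). Clock genes had 6 higher and 7 lower of 19 (15 adjusted over the list alone). BMAL1 had 2.15 ± 0.09, PER3 -2.32 ± 0.12, PER2 -2.11 ± 0.11 and BHLHE40 -2.05 ± 0.13 (adjusted p = 0.237). Contraction and relaxation receptors had 11 higher and 8 lower of 30 (21 adjusted over the list alone). PTGER2 had -2.01 ± 0.07 and the phosphodiesterase gene PDE4D -1.74 ± 0.12 (adjusted p = 0.726). Matrix genes had 11 higher and 3 lower of 30 (15 adjusted over the list alone). COL11A1 had 1.95 ± 0.08 and the elastin gene ELN 1.09 ± 0.17 (adjusted p = 0.220; adjusted p = 0.0236 without 4 h replicate 2). Proteases had 4 higher and 11 lower of 22 (16 adjusted over the list alone). ADAMTS5 had 2.38 ± 0.10 and MMP10 -3.03 ± 0.12 (adjusted p = 0.0772; 0.0448, 0.0463 and 0.0470 without 4 h replicate 3, 4 h replicate 4 and 24 h replicate 1). That list passed also with the normalization of the authors rebuilt (adjusted p = 0.0308), scaled to the array median (0.0469) and leaving out slide 1 (0.0479) or slide 2 (0.0416).

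Growth factors had 4 higher and 10 lower of 24 between the times (15 adjusted over the list alone). IGFBP2 had 2.32 ± 0.14, PDGFD 1.56 ± 0.10 and HBEGF -3.08 ± 0.08 (adjusted p = 0.102). TGF-beta, activin and BMP genes had 11 higher and 7 lower of 28 (20 adjusted over the list alone). BMP6 had 1.56 ± 0.14, NOG 1.23 ± 0.10 and FST -1.36 ± 0.07 (adjusted p = 0.417). Immediate early genes had 7 higher and 8 lower of 21 (16 adjusted over the list alone). NR4A3 had 1.79 ± 0.17, IER3 1.26 ± 0.09 and FOSB -2.60 ± 0.17 (adjusted p = 0.726). Amino acid enzymes had 7 higher and 4 lower of 23 (14 adjusted over the list alone). AASS had 1.08 ± 0.11 (adjusted p = 0.417). Receptor and steroid-handling genes had 4 higher and 4 lower of 18 (8 adjusted over the list alone). HSD11B1 had 1.51 ± 0.08 (adjusted p = 0.726). Stress response genes had 1 higher and 7 lower of 20 (8 adjusted over the list alone). TRIB3 had -1.01 ± 0.13 and HSPA1A 0.49 ± 0.07 (adjusted p = 0.237). None of 11 metallothioneins (MT1M -0.52 ± 0.35; adjusted p = 0.614 for the list) or 30 ribosomal protein genes (adjusted p = 0.652 for the list) passed, also adjusted over each list alone, while with the slide as a block 1 metallothionein was higher and 1 ribosomal protein gene lower.

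Among markers of other cell types, 3 of 11 epithelial markers were lower and 1 higher between the times (5 adjusted over the list alone). KRT18 had -1.50 ± 0.14 and MUC1 1.11 ± 0.19 (adjusted p = 0.102; 0.0495 without 24 h replicate 2 and 0.0308 with the normalization of the authors rebuilt). Fibroblast markers were higher in 4 of 12 cases (6 adjusted over the list alone). DPT had 1.16 ± 0.24 and PDGFRA 0.84 ± 0.06 (adjusted p = 0.186). Leukocyte markers had 2 higher and 2 lower of 11 (4 adjusted over the list alone). CD163 had 1.32 ± 0.23 and CSF1R -1.29 ± 0.13 (adjusted p = 0.726). Neural markers had 2 lower of 8 (2 adjusted over the list alone). GAP43, above background on 1 of 3 arrays at 24 h, had -2.96 ± 0.13 (adjusted p = 0.171). Endothelial markers had 1 higher of 7 (1 adjusted over the list alone), TEK at 0.40 ± 0.09 (adjusted p = 0.652). Single arrays ended the calls of KRT14 (-0.87 ± 0.26; adjusted p = 0.0531 without untreated replicate 2, 0.108 and 0.116 without 4 h replicates 3 and 4, 0.119 without 24 h replicate 1 or 3), CD68 (-0.29 ± 0.08; 0.0526, 0.0616 and 0.0515 without 4 h replicates 2, 3 and 4, 0.0615 and 0.0605 without 24 h replicates 2 and 3) and MFAP5 (0.47 ± 0.14; 0.111 and 0.106 without 4 h replicates 3 and 4, 0.103 and 0.0870 without 24 h replicates 1 and 3).

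Between 24 h and 4 h, 7083 genes differed (limma, Benjamini-Hochberg), 4111 higher and 2972 lower at 24 h, and 1374 by at least 2-fold (659 with normexp correction, 858 with the normalization of the authors rebuilt, 2542 with array weights). The balance turned with array weights, to 5719 higher and 6593 lower. Of all genes tested, 43.7% had no overlap between the arrays of both times, where chance gives 10%. With the slide as a block, 9517 genes passed, among them 6986 of the 7083. Of the 1064 genes higher at 4 h, 746 were also higher at 24 h, 215 were not called and 103 were lower. Of the 1155 genes lower at 4 h, 855 were also lower, 203 were not called and 97 were higher. Genes that were not called at 4 h but differed at 24 h from both untreated cells and the 4 h cells numbered 3149 higher and 1935 lower.

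Across genes, which are not independent replicates, the changes at 4 h and 24 h correlated at 0.547. Both share the untreated arrays, and simulated groups with no effect gave 0.431 on average. The simulated arrays were independent, so 0.431 leaves out the slide, with which 77.1% of the sum of squares within groups went. With different untreated arrays for each time the correlation was 0.318 to 0.513. The covariance with shared untreated arrays was 0.150, against 0.0239 in the simulations. It was 0.1004 to 0.1474 with different untreated arrays for each time.

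In the table of the authors, 2436 probes at 4 h (1263 higher, 1173 lower) and 11287 at 24 h (6729 higher, 4558 lower) had a deposited FDR under 0.05. Over the same probes, the deposited log2 changes correlated with those above at 0.931 for 4 h and 0.948 for 24 h, and 99.95% and 99.97% of the called genes had the same direction.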

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

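The tests of the number of genes with the slide as a block and without 24 h replicate 2, and of the genes with opposite directions with the slide as a block, were chosen after the result was seen. The other tests in this part were set before.

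Far more genes changed at 24 h than at 4 h, by a ratio of 4.01. The groups are spread unevenly over the slides, but the ratio was 2.99 with the slide as a block, which argues against the uneven spread as the whole cause. One array at 24 h, replicate 2, had 76 saturated spots, and without it the ratio was 4.19. A longer exposure to the drug may explain the difference in number, as a hypothesis drawn from these data. Neither this hypothesis nor an effect of the solvent was tested.

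Of the 35 splits of the arrays into groups of the same sizes, 1, the real one, gave 2219 genes or more at 4 h, and the highest other split gave 1. At 24 h, 1 of 35 splits gave 8896 genes or more, and the highest other split gave 1869 genes: it sets the arrays of slide 2 against the rest, and the count for the real groups with the slide as a block was 10692. Over all 35 splits the share was under 0.05 at both times. These splits move arrays freely between slides, with which 77.1% of the sum of squares within groups went. They therefore do not exclude chance. The splits that keep the number of arrays of each group on each slide, 12 at 4 h and 6 at 24 h, are too few for a share under 0.05. Between 24 h and 4 h the 10 splits are too few for a share under 0.05: the real split, 1 of the 10, gave 7083 genes and the highest other split gave 1.

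The cell cycle genes were lower at 24 h, with a median log2 change of -0.68 over 30 genes (adjusted p = 1.33e-10; adjusted p = 0.352 with an estimated correlation). Within slide 2 the median was -0.65 and within slide 3 it was -0.69, with 29 of 30 genes lower in each, so a difference between slides did not account for it. Under other scalings of the arrays the median was -0.66 (quantile normalization), -0.61 (array median) and -0.59 (normalization of the authors rebuilt). With normexp correction, which changes the background and keeps the scaling, it was -0.57, the value closest to 0. These values argue against the choice among these scalings as the cause. Each sets the arrays to a common level, so a shift shared by most genes could not be seen. An effect of the longer treatment may explain the fall of these genes, as a hypothesis, and since the list did not pass with an estimated correlation a fall beyond that of other genes is not established.

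Some genes moved in opposite directions at both times: 103 were higher at 4 h and lower at 24 h, and 97 were lower at 4 h and higher at 24 h. Independent lists of calls would give 179 and 251, so opposite directions were rarer than that. Genes higher at both times numbered 746 and genes lower at both 855, where independent lists would give 231 and 195. Both comparisons share the untreated arrays, so the calls are not independent. Of the 200 genes with opposite directions, 15 changed at least 2-fold at both times. The difference between the times itself was also called for them, which follows from how they were chosen, and it was -5.95 for HEYL (24 h minus 4 h) and -4.79 for XIRP1. The size of their fall at 24 h is uncertain. Their log2 signals were low there (HEYL -6.28 to -7.08, XIRP1 -6.18 to -6.71), and the deposited 24 h changes were -1.18 and -0.76. Against a difference between slides as the cause, 97% of the 200 genes kept both calls with the slide as a block. Whether 1 odd untreated array contributes to the opposite signs against untreated cells stays open. Both calls were kept by 69%, 67%, 64.5% and 80% without untreated replicates 1, 2, 3 and 4. The losses were thus similar without replicates 1, 2 and 3, and each of these fits had fewer untreated arrays, so the test cannot single out an array.

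In 2 of 44 groups of 4 untreated values, 1 array lay far from the others, where chance gives 2.2: untreated replicate 4 was at -5.91 for SPARCL1, against -5.67 for the nearest array, and at -4.31 for ZBTB16, against -3.22. Outside the main measurement, the E1A control spots had a median signal of at least 1003 on every array, against 1.35 to 1.91 for the negative controls.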

How the results depend on the processing

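Normexp correction, the rebuild of the authors' normalization, scaling to the array median, outlier spots kept, leaving out each slide and the slide block with an estimated correlation were tests chosen after seeing the data, and the others were set before. Planned values per sample by the authors were not run, since their table holds group means, and normexp was run on the median signal because the files hold no mean signal. Arrays with the same title number correlated at -0.773 to 0.302 after removal of group means (2 of 8 pairs over 0.1). Those with the same source name number correlated at -0.499 to 0.614 (5 of 9). No pair with the same title number shared a slide, and all pairs on different slides ranged from -0.773 to 0.529. These values therefore cannot tell whether the numbers pair the arrays, and the paired blocks are given as alternatives only. For the other values below, except where the construction is given, the cause was not tested. With the slide as a block 3572 genes changed at 4 h and 2 lists differed between the times, and under quantile normalization also 2. The paired block by title numbers gave 1376 genes at 4 h and 4628 between the times. Array weights gave 3414, 13603 and 12312 genes at 4 h, at 24 h and between the times. With fewer arrays, leaving out slide 1 gave 1008 genes at 4 h, leaving out slide 2 gave 4326 between the times, and leaving out slide 3 gave 1165 at 4 h and 4361 between the times. An estimated correlation left 2, 0 and 0 lists, with and without the slide block, and fry, which does not compare a list with other genes, called 19 at 24 h and 15 between the times. The correlation of the changes was 0.6179 with the paired block by source name numbers, 0.4769 with array weights and 0.318 at the lowest with the untreated arrays split. Leaving out 1 array gave 0.4025 (without 4 h replicate 2) to 0.618 (without untreated replicate 4). It gave 1608 to 2195 genes at 4 h, 7262 to 9312 at 24 h and 5433 to 7506 between the times, and 7 to 11, 10 to 13 and 3 to 6 lists. Of the results of named genes under 26 settings, 7427 kept their side of the threshold, 143 no longer passed and 18 passed anew. Among results past the threshold in either fit, 0 reversed direction, and leaving out slide 1 ended 24. A change of sign between fits that both missed the threshold counted as kept, and genes without a value under a setting were not counted. Signal over background limits genes with at-least values, of which there were 61 at 4 h, 162 at 24 h and 129 between the times.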

Other observations

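The tests of gene ontology terms followed the fixed lists, and the single genes below were chosen after their values were seen.

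Of 582 terms, camera called 7 at 4 h, 15 at 24 h and 21 between the times, and 0 at each with an estimated correlation. At 24 h, lysosome genes were higher in 51 of 109 cases and lower in 9 (adjusted p = 0.000909, 0.00419 with the slide as a block), with SORT1 at 2.56 and CTSD at 0.80. Genes for rRNA processing were lower in 26 of 48 cases and higher in 5 (adjusted p = 0.0302), with DKC1 at -0.69, NOP58 at -0.58 and NOP56 at -0.51. Peroxisome genes were higher in 33 of 75 cases and lower in 9 (adjusted p = 0.0302). Fatty acid metabolic genes were higher in 26 of 45 cases and lower in 5 (adjusted p = 0.0302), a call that ended with the slide as a block (adjusted p = 0.0769).

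At 4 h, genes of insulin receptor signaling were higher in 7 of 27 cases and lower in 0 (adjusted p = 0.0263), which ended with the slide as a block (adjusted p = 0.163). FOXO1 had 2.73 ± 0.08, PIK3R1 2.01 ± 0.13 and IRS2 1.95 ± 0.09. Genes for the inactivation of MAP kinases were lower in 5 of 17 cases and higher in 1 (adjusted p = 0.0263, 0.153 with the slide as a block), with DUSP6 at -2.94 ± 0.11.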
